A study of Homo sapiens with 36 samples.

How the data were processed

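Gene expression was measured with Illumina beadchips on 36 samples of WA09 human embryonic stem cells and their derivatives, in 12 groups of 3 arrays. Per the labels' protocols, the cells were grown on mouse feeder cells and plated on matrigel for differentiation, total RNA was extracted with Trizol and cleaned on columns with a DNase step, and biotinylated cRNA was hybridised. The groups were day 0, day 1, the DSi and NC conditions at days 3, 6, 8 and 11, and the BE condition at days 8 and 11. Groups and replicate numbers were taken from the labels. The labels of day 0 and day 1 name LDN-193189 and SB431542 but no condition, and both were treated as groups of their own. The title of DSi day 3 replicate 1 lacks a suffix that those of the other DSi arrays carry; its group was taken from the other labels.

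The deposited probe table gave, per the file headers, a mean bead signal for each of 47323 probes and each array, an intensity on a linear scale that had not been normalized between arrays. Beside each signal the deposited table gave, per the file headers, a detection p-value against the array's negative controls, as the scanner software writes it. A second deposited table held the authors' processed values for 34687 gene symbols. These deposited values were on the log2 scale and quantile normalized between arrays by the authors, as read from the values set against the probe signals of the same arrays: the sorted values of all arrays agreed, with a median of 6.723 and a maximum of 14.261 in every column. No background had been subtracted, and genes were not centred. The submitters' processing notes name Partek, without a version or a role; other details of these steps are not given in the sources used here. The probe table carried no gene names, no control probes and no slide names.

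Gene names were therefore carried over from the authors' values. A gene of their table was tied to a run of neighbouring probes where, on all 36 arrays, its values were those that 1 monotone function per array gave for the mean signal of these probes. For 33911 genes this held within a root mean square difference of 0.002 on the log2 scale, and 776 more lay between genes already tied; 0 genes were left without a probe. Of the probes 99.99% were tied (47316), 26219 genes to 1 probe and 8468 to several, up to 17, and 99.93% of neighbouring genes had their probes in the order of the table. Symbols were brought up to date through the RefSeq gene table of assembly GRCh38.p14, used for names only: 17585 were current, 2904 were updated through a synonym and 14198 were kept, among them 9823 that start with LOC and 3270 that start with HS. Of the genes named here, the table lists PMEL as SILV, HOATZ as C11ORF88 and POU5F1B as POU5F1P1. Where 2 genes are near-identical copies, such as POU5F1 and POU5F1B or LEFTY1 and LEFTY2, their probes may bind both transcripts.

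Signals were background-corrected with limma's normexp model, with negative controls inferred from the detection p-values and an offset of 16, quantile normalized and put on the log2 scale. Probes with a detection p under 0.05 on at least 3 arrays were kept (29106, of which 29104 were tied to a gene), and the probe with the highest mean stood for a gene, which left 22850 genes. Where a named gene passed and its probes disagreed in direction, this is said beside it. A linear model with a mean per group was fitted to all 36 arrays with limma, so that the groups shared 1 estimate of spread (24 residual degrees of freedom, median prior degrees of freedom 19.7, median residual SD 0.269), with empirical Bayes moderation and a trend of the prior variance. The 13 differences between groups and 2 differences of differences were tested two-sided, and p-values were adjusted over the genes of each comparison by the method of Benjamini and Hochberg; a gene counted as higher or lower with an adjusted p under 0.05. Fold changes are log2 differences of normalized signals, the first group minus the second, and are compressed by the offset for dim genes. Where a gene was not above background on any array of 1 group, its fold is written as "at least": the mean of the brighter group was set against, per array of the dimmer group, the higher of the gene's own signal and the lowest signal of a probe above background. Where it was above background on only 1 or 2 arrays of the lower group, the fitted difference is given with their number, and its size leans on signals at background. The replicates with the same number deviated together in the NC to DSi comparisons at days 3, 6 and 11, in BE to NC at day 11 and in BE to DSi at day 11, where the correlation of their deviations from the group means was above 0.1 for each of the 3 pairs (0.11 to 0.31), and in the other comparisons not for each pair. This pairing was read from the values, since the labels do not say what a shared number means.

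The 20 gene lists were pluripotency, Nodal and TGF-beta targets, BMP targets, WNT targets, anterior neural, posterior and HOX, neural crest, melanocyte, glia and Schwann cell, sensory neuron, pan-neuronal, placode, surface ectoderm, mesenchyme and fibroblast, mesoderm, endoderm, trophoblast, proliferation, stress response and hypoxia genes. Each list was tested with camera at a correlation between genes of 0.01, and again with the correlation estimated, and p-values were adjusted over the 300 tests of 20 lists in 15 comparisons. Of these, 123 passed with the preset correlation and 72 of them also with the estimated one; fry, which tests whether a list's genes move on balance one way, passed 151. Members of a list below background on all but a few arrays were not tested, among them SOX1 and 10 of the 16 posterior and HOX genes. Genes are named by a rule: per comparison the 5 largest changes in each direction among genes that passed, were detected on all 3 arrays of the higher group and changed the same way in all 3 differences between same-numbered arrays; up to 4 passing members per list; and in every comparison a fixed set of markers, among them POU5F1, NANOG, PAX6, SOX10, FOXD3, TFAP2A, MITF, DCT, AXIN2, LEF1, ID1 and ID3. Some genes named by this rule are not reported here. For differences of differences the 4 largest in each direction were taken. Symbols that name only a locus, XIST and Y-linked genes were left out. The groups, these 15 comparisons and their tests, the 20 lists, the rule and the alternatives were fixed before the data were examined. The tests of explanations, a retina list and the changes from day 3 to day 6 were added later, and the p-values of the list tests between these days were adjusted over 4 tests.

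The alternatives were no background correction, median scaling or cyclic loess in place of quantile normalization, the authors' values, no filter on dim probes and a stricter one (detection p under 0.01 on all 3 arrays of a group), the mean over a gene's probes, each probe on its own, the replicate number as a fixed or random block, only the arrays of the groups compared, array weights, no trend of the prior variance, a robust prior, a minimum change of 2-fold, and leaving out each array or each replicate number. Median scaling shifted the median of all genes by 0.272 between day 1 and day 0, 0.183 and 0.328 between DSi and NC day 3 and day 0, 0.164 and 0.108 between DSi and NC day 11 and day 0, 0.164 and -0.106 between BE and NC at days 8 and 11, -0.17 between BE and DSi, and -0.151 and -0.247 in the differences of differences; quantile normalization sets such shifts near 0, so changes are relative to the other genes. On simulated data for the NC to DSi comparison at day 11, with 22850 genes of which 50 per size were changed, the fit called 18% of changes of 0.5 on the log2 scale, 82% of 1, 100% of 2 and 100% of 3, and 14 of its 164 calls were unchanged genes. The simulated arrays were independent, with a single SD for each gene, and held fewer changed genes than the 2538 called in the data. These rates therefore need not hold for the data. R 4.3.3 with limma 3.58.1, statmod 1.5.0 and the data.table package (1.17.8), and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.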

Results

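Gene expression was measured on 36 Illumina expression beadchips hybridised with labelled cRNA from WA09 cells, an established human embryonic stem cell line. The arrays formed 12 groups of 3. Cells collected on days 0 and 1 formed a group each, and the source labels of all groups name embryonic stem cells. Cultures grown in 100 nM LDN-193189 and 10 µM SB431542, called DSi for dual SMAD inhibition and described in the labels as a central nervous system condition, were collected on days 3, 6, 8 and 11. LDN-193189 blocks type I receptors for bone morphogenetic proteins (BMPs), and SB431542 blocks those for activin, Nodal and TGF-beta. The NC (neural crest) cultures received in addition 3 µM CHIR 99021, an inhibitor of GSK3 that activates WNT signalling, and were collected on the same days. The BE (melanocyte) cultures received the NC compounds with 25 ng/ml BMP4 and 100 nM endothelin 3 (EDN3), the ligand of the receptor EDNRB, and were collected on days 8 and 11. The labels give day 0 and day 1 no condition of their own but name LDN-193189 and SB431542 for both, and whether the day 0 cells had received them is not stated, which bears on every comparison with day 0. Of the DSi arrays, day 3 replicate 1 lacks a suffix that the titles of all the others carry. What the suffix means is not stated, so this array may have been treated differently, which bears on every DSi day 3 value. The mean signal per array lay between 214.7 and 462.5, and 16055 to 19724 of the 47323 probes were detected (33.9 to 41.7%). Arrays of a group correlated at 0.972 to 0.987 over the log2 values. The array closest to each array belonged to its own group for 31 of the 36. The other 5 were day 3 arrays, each closest to the same-numbered array of the other condition at day 3. Titles of arrays with the same replicate number share a code, whose meaning is not stated. The first 3 principal components held 33.0, 16.5 and 7.10% of the variance. The number of arrays limits the precision, and the origin of the replicates is not stated, so the p-values measure only the spread between these samples, which may be technical.

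The first comparison asked what changed within the first day. Direct targets of Nodal signalling were lower at day 1. LEFTY1, which encodes an extracellular Nodal antagonist and is itself induced by Nodal, fell by 6.01 on the log2 scale (SE 0.26, 2 of 3, adjusted p = 9.11e-22), from 11.55 ± 0.58 at day 0 to 5.54 ± 0.39 at day 1 (SD, n = 3; this n holds for every group). Beside an SE, 1 of 3 or 2 of 3 counts the arrays of the lower group above background. LEFTY2 and the ligand gene NODAL were not above background on any day 1 array, and their falls came to at least 51.0-fold and at least 6.66-fold. The BMP target ID1, an inhibitor of basic helix-loop-helix factors, fell by 3.54 (SE 0.31, 2 of 3, adjusted p = 1.43e-11), while its relatives ID3 and ID2 rose by 1.47 (SE 0.24) and 1.13 (SE 0.19). NPTX1, encoding neuronal pentraxin, rose by 6.71 (SE 0.48, 1 of 3, adjusted p = 3.91e-14) to 11.72 ± 1.43.

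In all, 1006 of 22850 genes differed between day 1 and day 0, 552 of them higher and 454 lower. Other large rises were those of CUZD1 (4.42, SE 0.30), the phosphatase inhibitor gene PPP1R1B (3.17, SE 0.31, 1 of 3), the carbonic anhydrase relative CA11 (2.98, SE 0.24, 1 of 3) and the tight junction gene TJP3 (2.76, SE 0.24). CER1, a secreted antagonist of Nodal and BMP, was at least 10.3-fold lower at day 1. Gene lists fixed beforehand were tested against the other genes; their calls also held with an estimated correlation between genes unless its adjusted p is given. Of the 9 Nodal and TGF-beta targets tested, 0 rose and 8 fell, with the same numbers adjusted over the list alone; the median was -3.07 and the list test gave an adjusted p of 5.47e-43. Among 17 pluripotency genes 1 rose and 3 fell, also adjusted over the list alone. The homeobox factor NANOG fell by 2.41 (SE 0.22, adjusted p = 7.12e-11) and the TGF-beta family member GDF3 by 1.43 (SE 0.19, 2 of 3), whereas POU5F1 stood at -0.75 (SE 0.30, adjusted p = 0.178, and 0.00651 on the authors' values). The pluripotency list as a whole had a median of -0.21 and an adjusted p of 0.0265, which was 0.252 with an estimated correlation, 0.113 without day 0 replicate 3 and 0.068 without day 1 replicate 2. Proliferation genes had a median of 0.35, with 3 of 14 higher and 5 adjusted over the list alone, BUB1 by 1.24 (SE 0.19). The adjusted p of that list was 0.000101, and 0.153 with an estimated correlation. The WNT feedback gene AXIN2 rose by 1.44 (SE 0.17, adjusted p = 7.19e-08), BAMBI, a decoy receptor gene of the TGF-beta family, fell by 2.12 (SE 0.29), and AFP and PDGFRB fell by 1.65 (SE 0.27) and 1.44 (SE 0.29). PAX6, SOX10, TFAP2A, MITF and DCT, which mark neural, neural crest and pigment cells, had log2 differences between -0.04 and 0.31, and no adjusted p below 0.61. The count fell to 610 without day 0 replicate 1, to 622 without day 0 replicate 2 and to 665 without day 1 replicate 3. With median scaling in place of quantile normalization the split was 849 higher and 372 lower (69.5% higher against 54.9%).

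By day 3 of dual SMAD inhibition, forebrain regulators had appeared while Nodal targets and part of the pluripotency genes had dropped. DLK1, a transmembrane relative of Notch ligands, rose by 7.25 (SE 0.31, 1 of 3, adjusted p = 1.63e-22) to 12.04 ± 0.76 (SD, n = 3), against 4.80 ± 0.31 at day 0. The forebrain homeobox gene SIX3 was at least 14.98-fold higher, and HESX1 and FEZF1, also transcription factors of the anterior neural plate, rose by 3.50 (SE 0.29) and 3.13 (SE 0.28, 1 of 3). NANOG was at least 19.2-fold lower and below background on all 3 arrays, and POU5F1 fell by 2.01 (SE 0.30, adjusted p = 1.58e-06) to 8.23 ± 0.68.

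DSi day 3 and day 0 differed in 3820 genes, 1993 higher and 1827 lower. The largest rises after DLK1 were NPTX1 (7.17, SE 0.48, 1 of 3), the secreted WNT antagonist FRZB (at least 43.8-fold), the LIM-only factor LMO1 (at least 42.2-fold) and VWF (at least 30.6-fold). The largest falls were LEFTY1 (at least 83.3-fold), LEFTY2 (-5.87, SE 0.34, 1 of 3), the peptide genes ADM (-5.63, SE 0.38) and NTS (at least 40.05-fold), and CAV1 (-5.56, SE 0.28). Anterior neural genes rose in 8 of 15 cases and fell in 0, also adjusted over the list alone, with a median of 1.04 and a list test of 1.31e-10. In the pluripotency list 2 rose and 9 fell (10 fell adjusted over the list alone; median -0.66, list test 8.54e-05); L1TD1 fell by 1.45 (SE 0.33) and GDF3 by 2.15 (SE 0.19, 1 of 3). The Nodal and TGF-beta targets fell in 8 of 9 cases, also adjusted over the list alone, with a median of -3.49 (list test 6.76e-23). The 8 BMP targets moved both ways: ID1 fell by 3.33 (SE 0.31), while ID2 and ID3 rose by 1.95 (SE 0.19) and 1.53 (SE 0.24). That list had a median of 0.04, a mean of -0.41 and an adjusted p of 0.997, with 3 higher and 2 lower on either adjustment. Stress response genes fell in 6 of 8 cases on either adjustment (median -0.85, list test 6.74e-05), among them TRIB3 by 2.25 (SE 0.31, 2 of 3), CHAC1 by 1.24 (SE 0.24, 2 of 3) and ATF3 by 1.16 (SE 0.23). SOX9 was at least 4.99-fold higher, EDNRB fell by 2.90 (SE 0.34), the melanosome matrix gene PMEL rose by 1.94 (SE 0.20), and the actin-binding TAGLN and the surface glycoprotein gene THY1 fell by 3.04 (SE 0.27) and 2.26 (SE 0.16). AFP was at least 24.6-fold lower. PAX6 stood at 0.38 (SE 0.23, adjusted p = 0.297) at this day, and at 0.69 (adjusted p = 0.0178) with median scaling.

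In NC, the condition with CHIR 99021, day 3 showed a rise of WNT targets against day 0 and, as in DSi, a fall of stem cell genes. Changes against day 0 hold those of time as well, and AXIN2 was already higher at day 1. SP5, a transcription factor gene induced by WNT signalling, was at least 9.88-fold higher than at day 0, where it was below background. The receptor gene TNFRSF19 rose by 4.35 (SE 0.29, 2 of 3, adjusted p = 5.39e-16), LEF1, a nuclear partner of beta-catenin, by 1.31 (SE 0.27, 2 of 3), and AXIN2 by 1.16 (SE 0.17, adjusted p = 9.72e-07). NANOG was at least 18.6-fold lower and POU5F1 fell by 2.13 (SE 0.30), to 8.11 ± 0.30 (SD, n = 3).

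A total of 4362 genes differed between NC day 3 and day 0, 2277 higher and 2085 lower; with median scaling the split was 3245 higher and 1834 lower (63.9% higher against 52.2%). DLK1 (7.36, SE 0.31, 1 of 3), NPTX1 (6.51, SE 0.48, 1 of 3), the matrix gene PAPLN (5.56, SE 0.30, 1 of 3), LMO1 (at least 34.3-fold) and FRZB (at least 32.8-fold) led the rises. The falls were led by LEFTY1 (at least 80.5-fold), ANXA1 (-6.30, SE 0.56, 1 of 3), LEFTY2 (at least 53.1-fold), NTS (at least 38.7-fold) and CAV1 (-5.71, SE 0.28, 2 of 3). WNT targets rose in 7 of 10 cases on either adjustment, over all genes or adjusted over the list alone (median 1.05, list test 3.43e-07). Pluripotency genes fell in 12 of 17 cases and rose in 2, on either adjustment (median -0.89, list test 2.26e-07), PHC1 by 1.76 (SE 0.19). Among the 9 Nodal and TGF-beta targets 8 fell and 0 rose, also adjusted over the list alone (median -3.48, list test 1.37e-20). Anterior neural genes rose in 5 cases and fell in 1 on either adjustment (median 0.35, list test 0.00188, adjusted p = 0.11 with an estimated correlation); OTX2 rose by 2.66 (SE 0.18) and FEZF1 by 2.11 (SE 0.28, 1 of 3), and SOX3 fell by 2.82 (SE 0.26). ID1 fell by 4.73 (SE 0.31, 1 of 3) and BAMBI by 4.68 (SE 0.29), while ID2 rose by 2.63 (SE 0.19). Over the 8 BMP targets the median was 0.37 and the mean -0.44, with an adjusted p of 0.867 (3 higher and 2 lower, and 4 higher and 2 lower adjusted over the list alone). Stress response genes fell in 5 of 8 cases, 6 adjusted over the list alone (median -0.62, list test 0.00042). SOX9 was at least 5.62-fold higher and the placode gene EYA2 rose by 2.84 (SE 0.27, 1 of 3).

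By day 11 the DSi cultures carried high levels of forebrain and eye field regulators and lower levels of most stem cell genes than day 0. LHX2, a LIM homeobox gene of the forebrain and optic vesicle, reached 12.06 ± 0.60 (SD, n = 3) and was at least 119.6-fold higher than at day 0. PAX6 rose by 6.52 (SE 0.23, 1 of 3, adjusted p = 2.45e-26), from 4.78 ± 0.33 to 11.30 ± 0.34, the Notch target HES5 was at least 138-fold higher, and the homeobox gene EMX2 rose by 5.82 (SE 0.32, 1 of 3). POU5F1 fell by 5.56 (SE 0.30, 1 of 3, adjusted p = 1.57e-19), and NANOG was at least 19.4-fold lower.

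In this comparison 6259 genes differed, 3141 higher and 3118 lower. DLK1 (8.29, SE 0.31, 1 of 3) and GAS1 (7.13, SE 0.22, 1 of 3), whose product binds hedgehog ligands, were among the largest rises. The largest falls were the neuropeptide gene GAL (at least 110.4-fold), the smooth muscle actin gene ACTG2 (-6.60, SE 0.41, 1 of 3), LEFTY1 (-6.23, SE 0.26, 2 of 3), GLIPR1L1 (at least 41.4-fold) and POU5F1B (-6.13, SE 0.33, 2 of 3), a near-identical copy of POU5F1 whose probe may also bind its transcript. Anterior neural genes rose in 13 of 15 cases and fell in 1, on either adjustment, with a median of 3.70 (list test 2.71e-19). Pluripotency genes fell in 13 of 17 cases and rose in 1, with the same numbers adjusted over the list alone (median -2.55, list test 1.32e-18); PRDM14 was at least 18.5-fold lower and L1TD1 fell by 4.31 (SE 0.33). Of the 8 BMP targets 7 rose and 1 fell, also adjusted over the list alone (median 1.26, list test 1.66e-05), ID2 by 4.52 (SE 0.19) and ID3 by 3.42 (SE 0.24), while BAMBI fell by 2.61 (SE 0.29). WNT targets rose in 5 of 10 cases on either adjustment (median 0.72, list test 0.000901), LEF1 by 3.18 (SE 0.27, 2 of 3). Pigment genes were also higher: DCT, dopachrome tautomerase, was at least 24.6-fold higher at 9.78 ± 0.51, TYRP1 at least 3.997-fold, and PMEL and MITF rose by 4.33 (SE 0.20) and 1.83 (SE 0.28, 1 of 3). In the melanocyte list 6 of 16 rose and 2 fell on either adjustment (median 0.37, list test 0.0159, adjusted p = 0.251 with an estimated correlation, and between 0.0521 and 0.0787 under 4 other settings); EDNRB fell by 2.97 (SE 0.34). SOX10, which marks neural crest, was detected on 0 of the 3 arrays, with a difference of -0.05 (SE 0.24, adjusted p = 0.912). MSX1 rose by 4.16 (SE 0.22, 1 of 3), TFAP2A was at least 3.51-fold higher, and the brain lipid-binding protein gene FABP7, typical of radial glia, at least 16.1-fold. Of 10 pan-neuronal genes 3 rose and 1 fell, also adjusted over the list alone (median 0.23, adjusted p = 0.435), NEFM by 2.57 (SE 0.34, 1 of 3) and DCX by 1.75 (SE 0.30, 1 of 3).

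The NC cultures at day 11 combined neural crest, sensory neuron and general neuronal genes. POU4F1 (BRN3A), a sensory neuron homeobox gene, was at least 86.2-fold higher than at day 0 and stood at 11.59 ± 0.36 (SD, n = 3). SOX10, which is required in the neural crest lineage, was at least 33.4-fold higher, TFAP2B at least 38.4-fold, and the crest and dorsal neural tube gene MSX1 rose by 6.57 (SE 0.22, 1 of 3, adjusted p = 1.56e-26). STMN2, a neuronal microtubule regulator, rose by 5.46 (SE 0.37, adjusted p = 2.25e-16) to 11.99 ± 0.47, and the synaptotagmin gene SYT4 by 6.03 (SE 0.32, 1 of 3).

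Between NC day 11 and day 0, 6715 genes differed, 3424 higher and 3291 lower; the orphan nuclear receptor gene NR2F1 was at least 57.5-fold higher. Of 18 neural crest genes 14 rose and 1 fell (16 and 1 adjusted over the list alone; median 2.32, list test 3.36e-16), TFAP2A by at least 21.3-fold. All 10 pan-neuronal genes tested rose on either adjustment (median 3.86, list test 9.41e-16), DCX by 4.76 (SE 0.30, 1 of 3) and NEFM by 4.66 (SE 0.34, 1 of 3). Sensory neuron genes rose in 7 of 9 cases, also adjusted over the list alone (median 0.90, list test 1.41e-08), among them ISL1 (5.24, SE 0.28), the proneural gene NEUROG1 (4.39, SE 0.28, 1 of 3) and NEUROD1 (3.25, SE 0.21, 2 of 3). Placode genes rose in 5 of 7 cases, 6 adjusted over the list alone (median 1.67, list test 1.24e-05), EYA2 by 5.82 (SE 0.27, 1 of 3). All 10 WNT targets tested rose on either adjustment (median 3.29, list test 5.55e-16): TNFRSF19 by 5.56 (SE 0.29, 2 of 3), LEF1 by 4.31 (SE 0.27, 2 of 3), AXIN2 by 2.97 (SE 0.17), and APCDD1 and SP5 by at least 30.4-fold and 13.2-fold. In the glia and Schwann cell list 5 of 7 rose and 1 fell on either adjustment (median 1.41, list test 0.0129, and 0.12 with the stricter detection filter); MBP was at least 7.92-fold lower. Pluripotency genes fell in 14 of 17 cases and rose in 1 (15 fell and 1 rose adjusted over the list alone; median -2.50, list test 3.37e-20); POU5F1 was at least 34.4-fold lower, and PODXL, a sialomucin abundant on stem cells, fell by 6.70 (SE 0.17). PAX6 rose by 3.77 (SE 0.23, 1 of 3) and SOX3 fell by 3.14 (SE 0.26), and the anterior neural list, with 4 higher and 3 lower on either adjustment, had a median of 0.02 (adjusted p = 0.793). ID1 stood at -0.17 (SE 0.31, adjusted p = 0.775).

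In the BE cultures at day 11, pigment cell genes were among the leading rises over day 0. MLANA, a melanosome antigen, rose by 6.32 (SE 0.24, 1 of 3, adjusted p = 3.67e-25) to 11.14 ± 0.28 (SD, n = 3), and the melanin synthesis genes TYRP1 and DCT were at least 47.4-fold and at least 26.7-fold higher. MITF, the main regulator of the melanocyte lineage, rose by 3.75 (SE 0.28, 1 of 3, adjusted p = 4.12e-15). SOX10 was at least 30.1-fold higher and the crest transcription factor SNAI2 at least 32.5-fold.

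The BE day 11 arrays differed from day 0 in 6583 genes, 3312 higher and 3271 lower. Melanocyte genes rose in 14 of 16 cases and fell in 0 on either adjustment (median 2.63, list test 2.23e-19), PMEL by 5.35 (SE 0.20). Neural crest genes rose in 14 of 18 cases and fell in 0, also adjusted over the list alone (median 2.08, list test 1.32e-17), MSX1 by 6.84 (SE 0.22, 1 of 3) and TFAP2A by at least 44.0-fold. BMP targets rose in 7 of 8 cases on either adjustment (median 1.99, list test 9.92e-09), ID2 by 4.84 (SE 0.19), ID3 by 2.97 (SE 0.24), SMAD6 by 2.37 (SE 0.25) and ID1 by 1.31 (SE 0.31). WNT targets rose in 9 of 10 cases on either adjustment (median 3.19, list test 3.86e-15), with DKK1, a secreted WNT antagonist and target, at least 55.7-fold higher. Pluripotency genes fell in 15 of 17 cases (0 rose, and 1 rose adjusted over the list alone; median -2.46, list test 2.11e-21). Markers of other cell types were measured beside these: the homeobox gene PITX1 was at least 38.6-fold higher, the mesoderm gene HAND1 at least 28.4-fold, the collagen gene COL3A1 at least 39.7-fold, and ISL1 rose by 4.87 (SE 0.28). Surface ectoderm genes rose in 5 of 6 cases and fell in 1 on either adjustment (median 2.01, list test 0.000937, adjusted p = 0.0832 with an estimated correlation), the keratin gene KRT7 by 2.47 (SE 0.29, 1 of 3) and GATA3 by at least 4.66-fold. The myelin gene PMP22 rose by 4.75 (SE 0.30), and the stress response gene ASNS, asparagine synthetase, fell by 3.38 (SE 0.20).

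**Figure D1:**
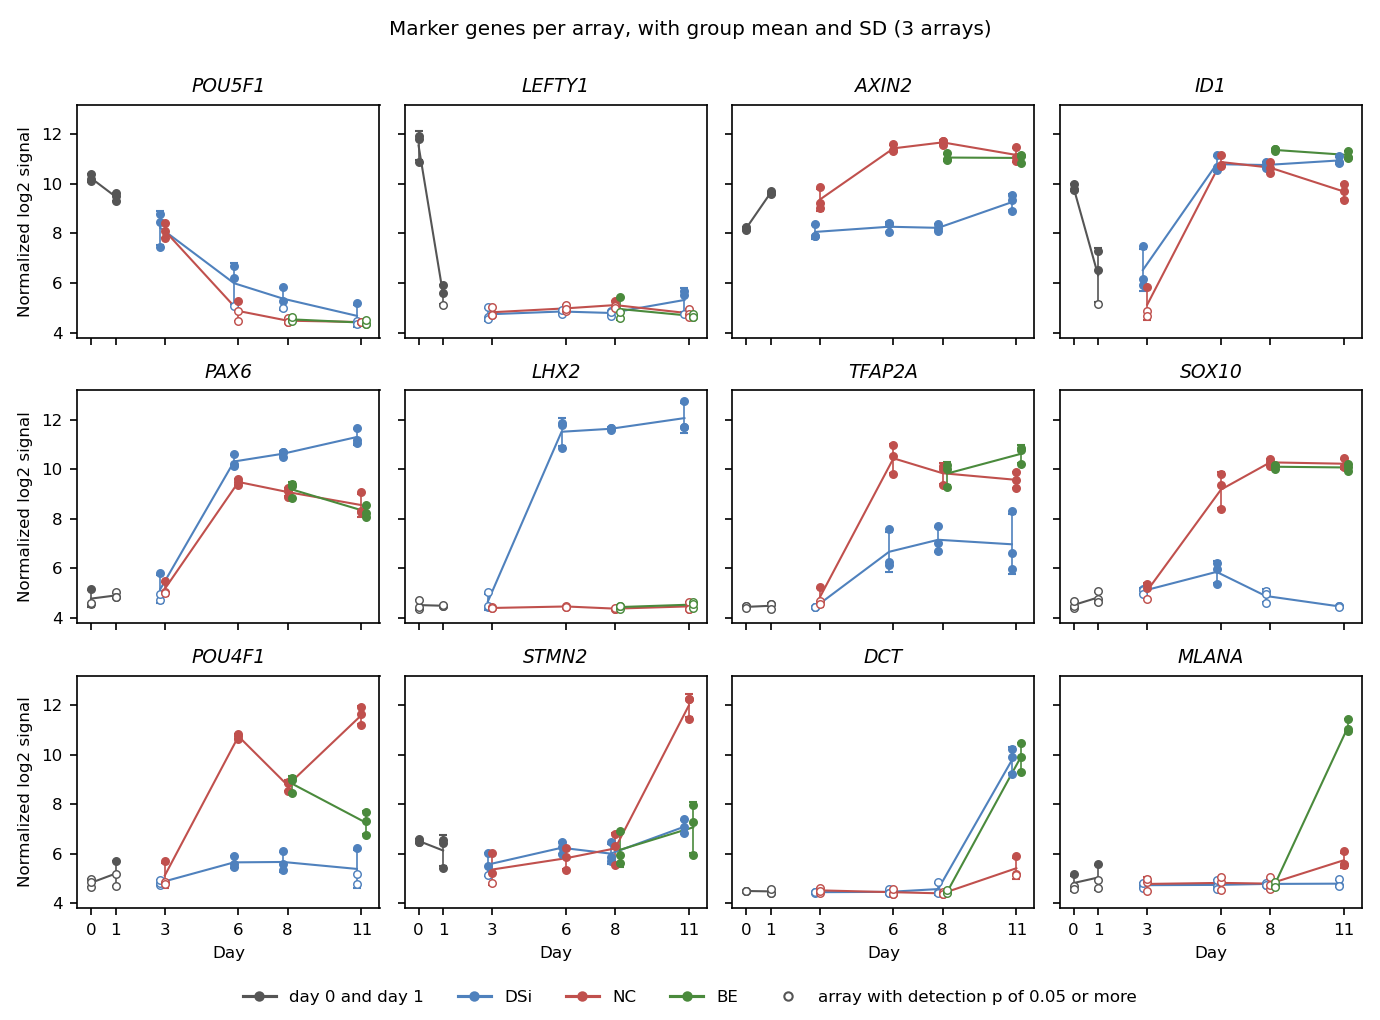
Normalized log2 signal (vertical axis) of 12 marker genes on each of the 36 arrays by day of collection (horizontal axis), grey for day 0 and day 1, blue for DSi, red for NC and green for BE. Small points are arrays, lines join group means, bars are SD over 3 arrays, and open points are arrays with a detection p of 0.05 or more. LHX2 reached 12.06 in DSi at day 11 and stayed near 4.47 in NC, SOX10 reached 10.22 in NC and 10.07 in BE, and MLANA reached 11.14 in BE.

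By the labels the NC and DSi cultures differ by CHIR 99021, so their comparison asks what changed with this compound added to dual SMAD inhibition. Nearly all DSi titles carry a suffix that the NC titles lack. Its meaning and the timing of the compounds are not stated, so the treatments may have differed in other ways as well. At day 3 the difference was small and ran along WNT targets and forebrain genes. SP5 was higher in NC by 3.12 (SE 0.30, 2 of 3, adjusted p = 4.13e-09), at 8.47 ± 0.60 against 5.35 ± 0.76 (SD, n = 3), and AXIN2 by 1.30 (SE 0.17, adjusted p = 5.45e-06). SIX3 had a difference of -4.18 (SE 0.29, 1 of 3, adjusted p = 1.33e-13), at 4.89 ± 0.47 in NC and 9.07 ± 0.68 in DSi, and SOX3 one of -2.28 (SE 0.26, adjusted p = 2.11e-07). DACT1, a modulator of WNT signalling, was higher by 2.06 (SE 0.29, 1 of 3, adjusted p = 2.25e-05).

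At this day 111 genes differed, 61 higher and 50 lower in NC. Fits without DSi day 3 replicate 1 and without NC day 3 replicate 3 called 71 and 64 genes. Of the 111 calls, 19, 68 and 44 were kept without replicate numbers 1, 2 and 3 of all groups, which also lowers the power. With only the compared arrays in the fit, 38 were kept. Of 10 WNT targets 3 were higher, and 6 adjusted over the list alone (median 0.73, list test 2.49e-18). Of 15 anterior neural genes 4 were lower, and 6 adjusted over the list alone (median -0.27, list test 7.95e-13). Of 17 pluripotency genes 2 were lower on either adjustment (median -0.22, list test 0.00115, but 0.0918 with an estimated correlation and 0.101 without DSi day 3 replicate 2). Of 18 neural crest genes 0 differed on either adjustment (median 0.04, adjusted p = 0.192, but 0.0322 with median scaling and 0.0104 with cyclic loess). SOX10, FOXD3, PAX6 and ID3 had differences of 0.01, 0.01, 0.01 and 0.08, with adjusted p-values of 0.999 or more, and LEF1 had 0.84 (SE 0.27, adjusted p = 0.259).

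At day 6 neural crest regulators were higher in NC and eye field and forebrain genes lower. WNT1, expressed in the dorsal neural tube, was at least 32.8-fold higher in NC, and POU4F1 was higher by 5.08 (SE 0.29, adjusted p = 7.69e-18), at 10.74 ± 0.09 against 5.66 ± 0.24 (SD, n = 3). TFAP2B was at least 15.2-fold higher, and MSX1, the endothelin receptor gene EDNRA and TFAP2A were higher by 4.31 (SE 0.22), 4.29 (SE 0.27, 1 of 3) and 3.77 (SE 0.36). LHX2 was at least 80.9-fold lower in NC, SIX3 at least 21.6-fold and HESX1 at least 13.01-fold, and the eye field gene RAX had a difference of -4.97 (SE 0.33, 1 of 3, adjusted p = 1.24e-15).

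Day 6 gave 1230 genes, 610 higher and 620 lower in NC. Neural crest genes were higher in 11 of 18 cases, 12 adjusted over the list alone, and lower in 0 (median 1.45, list test 1.68e-32), SOX10 by 3.32 (SE 0.24) and FOXD3 by at least 3.21-fold. Anterior neural genes were lower in 11 of 15 cases and higher in 0 (11 and 1 adjusted over the list alone; median -1.64, list test 4.25e-30). WNT targets were higher in 6 of 10 cases, 8 adjusted over the list alone (median 1.88, list test 3.06e-21): AXIN2 by 3.16 (SE 0.17), TNFRSF19 by 2.95 (SE 0.29), NKD1 by at least 4.93-fold, APCDD1 by 2.62 (SE 0.33, 2 of 3) and LEF1 by 1.55 (SE 0.27). The Notch target HES5 and the proneural gene NEUROG2 had differences of -4.23 (SE 0.39, 2 of 3) and -2.97 (SE 0.34, 2 of 3). ERBB3, a receptor of the neuregulin pathway in crest and glia, was higher by 1.51 (SE 0.26), TFAP2C by 1.66 (SE 0.29) and the collagen gene COL1A2 by 1.90 (SE 0.20). Pluripotency genes were lower in 6 of 17 cases, 9 adjusted over the list alone (median -0.44, list test 3.47e-05). ID1 and MITF had differences of 0.09 (adjusted p = 0.949) and 0.06 (adjusted p = 0.964).

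At day 8 SOX10 stood at 10.28 ± 0.14 in NC (SD, n = 3) and was below background on all 3 DSi arrays, a difference of at least 35.6-fold. LMX1A, a roof plate homeobox gene, was at least 35.5-fold higher in NC, EDNRA by 5.18 (SE 0.27, adjusted p = 3.27e-19), and WNT1 by at least 25.7-fold. LHX2 was at least 90.7-fold lower and RAX at least 49.9-fold, while HES5 and the neural progenitor gene SOX21 had differences of -6.41 (SE 0.39, adjusted p = 3.08e-17) and -5.39 (SE 0.27, adjusted p = 9.74e-20).

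Of 1527 genes, 767 were higher and 760 lower in NC. Neural crest genes were higher in 14 of 18 cases, 16 adjusted over the list alone, and lower in 0 (median 1.97, list test 2.54e-43), MSX1 by 4.73 (SE 0.22), TFAP2B by 4.58 (SE 0.25, 1 of 3) and SNAI2 by 4.06 (SE 0.23). Anterior neural genes were lower in 13 of 15 cases, 14 adjusted over the list alone (median -2.56, list test 1.77e-44), among them DLK1 (-4.73, SE 0.31) and PAX6 (-1.55, SE 0.23). WNT targets were higher in 7 of 10 cases on either adjustment (median 2.12, list test 8.94e-20), TNFRSF19 by 3.85 (SE 0.29) and AXIN2 by 3.45 (SE 0.17). EDNRB and ERBB3 were higher by 3.55 (SE 0.34) and 3.57 (SE 0.26). POU4F1 and GAP43, a growth cone protein gene, were higher by 3.09 (SE 0.29) and 2.69 (SE 0.25), and NEUROG2 had a difference of -2.35 (SE 0.34, 2 of 3). Mesenchyme and fibroblast genes were higher in 7 of 12 cases, 8 adjusted over the list alone, and lower in 1 (median 0.90, list test 5.97e-06), COL1A2 by 2.32 (SE 0.20). The cardiac actin gene ACTC1 was higher by 4.85 (SE 0.33) on its brightest probe, a direction shared by 1 of its 2 probes. MITF and DCT differed by -0.24 (adjusted p = 0.804) and -0.17 (adjusted p = 0.855).

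At day 11 the NC cultures differed from DSi by neuronal genes as well. POU4F1 was higher by 6.20 (SE 0.29, 1 of 3, adjusted p = 2.50e-21) at 11.59 ± 0.36 against 5.39 ± 0.75 (SD, n = 3), SYT4 by 6.04 (SE 0.32, 1 of 3), ISL1 by 5.42 (SE 0.28, 2 of 3) and STMN2 by 4.89 (SE 0.37, adjusted p = 2.62e-14). SOX10 was at least 33.5-fold higher. LHX2 was at least 122.2-fold lower, DLK1 had a difference of -7.15 (SE 0.31, adjusted p = 2.16e-22), and PAX6 one of -2.75 (SE 0.23), at 8.56 ± 0.46 against 11.30 ± 0.34.

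At day 11 2538 genes differed between the conditions, 1268 higher and 1270 lower in NC. All 10 pan-neuronal genes tested were higher on either adjustment (median 3.03, list test 2.36e-29), the RNA-binding protein gene ELAVL3 by 4.21 (SE 0.23, 1 of 3) and GAP43 by 3.07 (SE 0.25). Sensory neuron genes were higher in 5 of 9 cases, 7 adjusted over the list alone (median 0.80, list test 2.39e-13), NEUROG1 by 4.12 (SE 0.28, 1 of 3) and NEUROD1 by 3.07 (SE 0.21, 2 of 3). Neural crest genes were higher in 14 of 18 cases, 16 adjusted over the list alone (median 1.43, list test 4.78e-25), TFAP2B by 4.64 (SE 0.25), INSC by at least 10.7-fold and SNAI2 by 3.81 (SE 0.23, 1 of 3). Placode genes were higher in 4 of 7 cases on either adjustment (median 0.76, list test 0.000154), EYA2 by 2.14 (SE 0.27). In the glia and Schwann cell list 4 of 7 were higher and 1 lower on either adjustment (median 0.64, list test 0.00538, and 0.0751 with the stricter detection filter), ERBB3 by 3.68 (SE 0.26, 2 of 3), with FABP7 at -1.79 (SE 0.27). WNT targets were higher in 9 of 10 cases on either adjustment (median 1.86, list test 7.58e-19), APCDD1 by 4.45 (SE 0.33, 2 of 3), SP5 by at least 13.2-fold, NKD1 by 3.04 (SE 0.24, 1 of 3) and AXIN2 by 1.90 (SE 0.17). Anterior neural genes were lower in 14 of 15 cases on either adjustment (median -3.67, list test 2.73e-41), EMX2 with -4.33 (SE 0.32). BMP targets were lower in 6 of 8 cases and higher in 2 on either adjustment (median -1.03, list test 0.0017, adjusted p = 0.151 with an estimated correlation), ID3 with -1.53 (SE 0.24) and ID1 with -1.26 (SE 0.31). In the melanocyte list 5 of 16 were higher and 4 lower on either adjustment (median 0.09, mean -0.09, adjusted p = 0.96): EDNRB was higher by 3.25 (SE 0.34), while DCT and TYRP1 had differences of -4.36 (SE 0.25, 2 of 3) and -2.33 (SE 0.29, 1 of 3). LEFTY2 had a difference of -3.42 (SE 0.34, 1 of 3), with 8.48 ± 0.40 in DSi and 5.05 ± 0.48 in NC; its probe may also bind its close paralog LEFTY1. MITF differed by 0.09 (SE 0.28, adjusted p = 0.918).

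The calls between NC and DSi at successive days overlapped. They compare different arrays, but share 1 fit and its estimate of spread for each gene, so the numbers for independent lists are only a guide. Of the genes higher in NC, 23 were called on both day 3 and day 6 (1.60 for independent lists), 285 on day 6 and day 8 (20.5) and 410 on day 8 and day 11 (42.6); of those lower in NC the numbers were 19 (1.40), 315 (20.6) and 443 (42.2). On all of days 6, 8 and 11, 168 genes were higher and 219 lower. Of the genes higher in NC at day 6, 215 were higher and 25 lower at day 11. Of those lower at day 6, 277 were lower and 39 higher. The difference itself changed between day 3 and day 11 in 1240 genes, 660 toward higher and 580 toward lower in NC by the interaction term; with median scaling the split was 484 higher and 536 lower (47.5% higher against 53.2%). Neural crest genes moved up in 11 of 18 cases, 14 adjusted over the list alone (median 1.40, list test 2.00e-21), pan-neuronal genes in 8 of 10, 10 adjusted over the list alone (median 2.68, list test 1.93e-25). Anterior neural genes moved down in 12 of 15 and up in 1, 13 and 1 adjusted over the list alone (median -1.88, list test 2.20e-25).

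**Figure D2:**
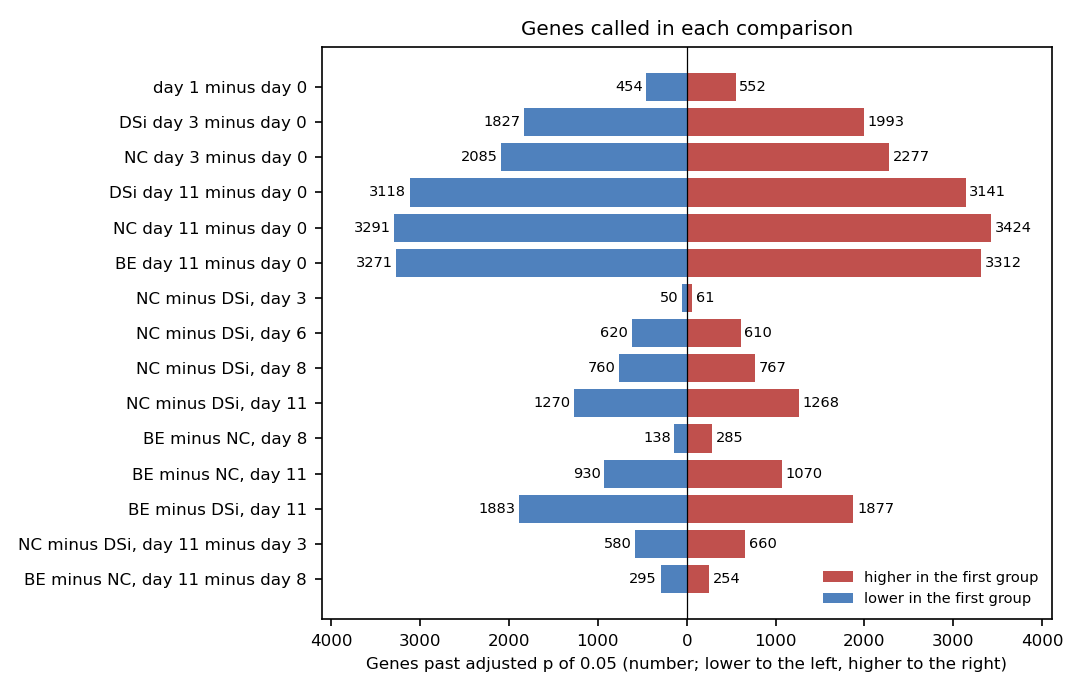
Number of genes past an adjusted p of 0.05 in each of the 15 comparisons (horizontal axis), with genes higher in the first group to the right in red and genes lower to the left in blue. For the last 2 comparisons higher and lower refer to the change of the difference between the days. NC and DSi differed in 111 genes at day 3 and in 2538 at day 11.

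The comparison of BE with NC asks what changed where BMP4 and EDN3 were given besides the NC compounds. The labels do not give the timing of the compounds, so whether LDN-193189 was present together with BMP4 is not known. At day 8 the leading gene was HAND1, a mesoderm and extraembryonic transcription factor gene, higher in BE by 4.56 (SE 0.37, adjusted p = 3.16e-12) at 10.47 ± 0.50 against 5.92 ± 0.54 (SD, n = 3). The carbonic anhydrase gene CA4 was at least 12.5-fold higher, and the BMP feedback gene SMAD6 was higher by 1.88 (SE 0.25, adjusted p = 1.99e-06). The chemokine receptor gene CXCR4 had a difference of -3.38 (SE 0.37, 1 of 3, adjusted p = 1.23e-08), and SP5 and WNT1 had differences of -2.41 (SE 0.30, 2 of 3) and -1.94 (SE 0.35).

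At day 8 423 genes differed, 285 higher and 138 lower in BE. With median scaling the split was 329 higher and 100 lower (76.7% higher against 67.4%). Fits without NC day 8 replicate 2 and without BE day 8 replicate 2 called 254 and 277. BMP targets were higher in 4 of 8 cases, 5 adjusted over the list alone (median 0.69, list test 5.46e-12), SMAD9 by 1.61 (SE 0.24). Proliferation genes were lower in 3 of 14 cases, 8 adjusted over the list alone (median -0.49, list test 5.97e-12). Among WNT targets DKK1 was higher by 2.60 (SE 0.40) and NKD1 had a difference of -1.88 (SE 0.24). Of the 4 mesoderm genes tested 1, HAND1, was higher on either adjustment (median 0.12, list test 0.00184, and 0.0542 without the filter on dim probes). Other large rises were HOATZ (at least 8.70-fold), the amino acid transporter gene SLC7A7 (3.24, SE 0.26) and SLN, encoding sarcolipin (3.22, SE 0.35), and large falls were HES6 (-2.41, SE 0.30) and NTM (-1.99, SE 0.26, 2 of 3). MSX2, ISL1 and COL3A1 were higher by 1.76 (SE 0.30), 2.28 (SE 0.28) and 2.61 (SE 0.30), PITX1 by at least 3.80-fold, and PMEL by 1.37 (SE 0.20). SOX10, TFAP2A and DCT had differences of -0.18 (adjusted p = 0.911), -0.01 (adjusted p = 0.997) and 0.05 (adjusted p = 0.986).

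By day 11 BE differed from NC by pigment genes on one side and neuronal genes on the other. TYRP1 was higher in BE by 5.90 (SE 0.29, 1 of 3, adjusted p = 3.20e-20), at 10.73 ± 0.53 against 4.83 ± 0.37 (SD, n = 3), MLANA by 5.40 (SE 0.24), DCT by 4.48 (SE 0.25, 2 of 3), tyrosinase (TYR) by 4.28 (SE 0.21, 2 of 3) and MITF by 1.83 (SE 0.28, adjusted p = 3.01e-06). STMN2 had a difference of -4.91 (SE 0.37, adjusted p = 3.75e-14), the migrating neuron gene DCX one of -4.57 (SE 0.30, 1 of 3), and POU4F1 one of -4.33 (SE 0.29). SOX10 was alike in size, at 10.07 ± 0.13 in BE and 10.22 ± 0.20 in NC (difference -0.15, SE 0.24, adjusted p = 0.849).

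A total of 2000 genes differed at day 11, 1070 higher and 930 lower in BE. Melanocyte genes were higher in 15 of 16 cases and lower in 1 on either adjustment (median 1.85, list test 2.31e-35). All 10 pan-neuronal genes tested were lower on either adjustment (median -3.33, list test 2.10e-32), NEFM with -4.34 (SE 0.34, 1 of 3) and ELAVL3 with -4.31 (SE 0.23, 1 of 3). Sensory neuron genes were lower in 4 of 9 cases and higher in 1 (6 and 1 adjusted over the list alone; median -0.58, list test 2.82e-08), NEUROG1 with -4.06 (SE 0.28) and NEUROD1 at least 9.30-fold lower. BMP targets were higher in 6 of 8 cases on either adjustment (median 1.43, list test 9.91e-10): BAMBI by 2.26 (SE 0.29), SMAD9 by 2.19 (SE 0.24, 1 of 3), SMAD6 by 1.99 (SE 0.25), ID1 by 1.47 (SE 0.31) and ID3 by 1.08 (SE 0.24). Neural crest genes were higher in 3 of 18 cases and lower in 3 (6 and 3 adjusted over the list alone; median 0.03, adjusted p = 0.298, and 0.0103 with each probe tested on its own), with MSX2 higher by 2.09 (SE 0.30), SNAI2 by 1.48 (SE 0.23) and ETS1 by 1.42 (SE 0.20). Placode genes moved both ways, 3 higher and 3 lower (3 and 4 adjusted over the list alone; median -0.71, mean 0.00, adjusted p = 0.178, and 0.0104 with each probe tested on its own): PITX1 was higher by 5.20 (SE 0.20, 2 of 3), and EYA2 had a difference of -3.14 (SE 0.27). Genes of other cell types were higher in BE. HAND1 was higher by 4.63 (SE 0.37, 1 of 3), and mesenchyme and fibroblast genes were higher in 4 of 12 cases on either adjustment (median 0.29, list test 1.01e-05), COL3A1 by 3.92 (SE 0.30) and LUM, encoding lumican, by 2.91 (SE 0.26). Surface ectoderm genes were higher in 3 of 6 cases, 4 adjusted over the list alone (median 0.72, list test 0.000252, adjusted p = 0.0511 with an estimated correlation), GATA3 by 2.16 (SE 0.31, 2 of 3). Trophoblast genes were higher in 5 of 7 cases on either adjustment (median 1.02, list test 3.01e-05, adjusted p = 0.0636 with an estimated correlation), the placental growth factor gene PGF by 1.69 (SE 0.26). DKK1 was higher by 3.24 (SE 0.40), the neuroendocrine factor INSM1 had a difference of -4.49 (SE 0.26, 2 of 3), troponin TNNC2 one of -4.63 (SE 0.20, 1 of 3), and NTN5 was at least 20.3-fold lower. AXIN2, LEF1 and PAX6 had differences of -0.12, -0.03 and -0.26, with adjusted p-values of 0.826, 0.985 and 0.655.

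The BE to NC difference changed between day 8 and day 11 in 549 genes, 254 toward higher and 295 toward lower in BE by the interaction term; with median scaling the split was 153 higher and 354 lower (30.2% higher against 46.3%). Melanocyte genes moved up in 8 of 16 cases, 12 adjusted over the list alone (median 1.26, list test 1.81e-31). Pan-neuronal genes moved down in 10 of 10 cases on either adjustment (median -2.90, list test 3.79e-38), and sensory neuron genes in 4 of 9, also adjusted over the list alone (median -0.72, list test 4.07e-15).

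BE and DSi at day 11 set the melanocyte against the central nervous system condition. MLANA was at least 63.3-fold higher in BE, PITX1 at least 38.7-fold and SOX10 at least 30.1-fold, and SNAI2 and the matrix proteoglycan gene BCAN were higher by 5.30 (SE 0.23, 1 of 3, adjusted p = 2.62e-22) and 5.30 (SE 0.30, 1 of 3, adjusted p = 1.08e-18). LHX2 was at least 123-fold lower, HES5 had a difference of -6.77 (SE 0.39, 1 of 3, adjusted p = 1.91e-18), and the forebrain zinc finger gene SP8 was at least 35.7-fold lower. DCT did not separate these conditions, at 9.90 ± 0.58 in BE and 9.78 ± 0.51 in DSi (SD, n = 3; difference 0.12, SE 0.25, adjusted p = 0.843).

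A total of 3760 genes differed, 1877 higher and 1883 lower in BE. Melanocyte genes were higher in 13 of 16 cases on either adjustment (median 1.97, list test 1.46e-22), TYR by 4.56 (SE 0.21, 1 of 3), EDNRB by 4.52 (SE 0.34), the pigment transporter gene SLC45A2 by 3.77 (SE 0.23, 1 of 3) and MITF by 1.92 (SE 0.28). Neural crest genes were higher in 12 of 18 cases and lower in 1 (14 and 1 adjusted over the list alone; median 1.80, list test 1.50e-21), INSC by at least 13.98-fold and TFAP2A by 3.65 (SE 0.36). Anterior neural genes were lower in 14 of 15 cases on either adjustment (median -3.38, list test 8.88e-33), with DLK1 at -5.85 (SE 0.31), RAX at -5.18 (SE 0.33, 1 of 3) and PAX6 at -3.00 (SE 0.23). WNT targets were higher in 9 of 10 cases on either adjustment (median 2.06, list test 1.02e-15), APCDD1 by 5.19 (SE 0.33, 2 of 3) and NKD1 by 3.05 (SE 0.24, 1 of 3). In the glia and Schwann cell list 5 of 7 were higher and 1 lower on either adjustment (median 1.99, list test 0.000109), PMP22 by 3.37 (SE 0.30), with FABP7 at -3.61 (SE 0.27). Of 8 BMP targets 2 were higher and 0 lower (2 and 1 adjusted over the list alone; median 0.31, adjusted p = 0.0822, but 0.0105 with fry); BAMBI was higher by 3.65 (SE 0.29), and ID1 and ID3 had differences of 0.22 (adjusted p = 0.742) and -0.45 (adjusted p = 0.225). The list of BMP targets passed without DSi day 11 replicate 3, with an adjusted p of 0.00524. Surface ectoderm genes were higher in 5 of 6 cases, 6 adjusted over the list alone (median 1.42, list test 3.34e-07), KRT7 by at least 4.11-fold. Mesenchyme and fibroblast genes were higher in 5 of 12 cases, 6 adjusted over the list alone with 1 lower (median 0.58, list test 4.65e-06), COL3A1 by 4.82 (SE 0.30, 1 of 3). HAND1 was at least 28.5-fold higher, ISL1 higher by 5.04 (SE 0.28, 2 of 3), and the replication gene MCM2 had a difference of -1.62 (SE 0.19).

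**Figure D3:**
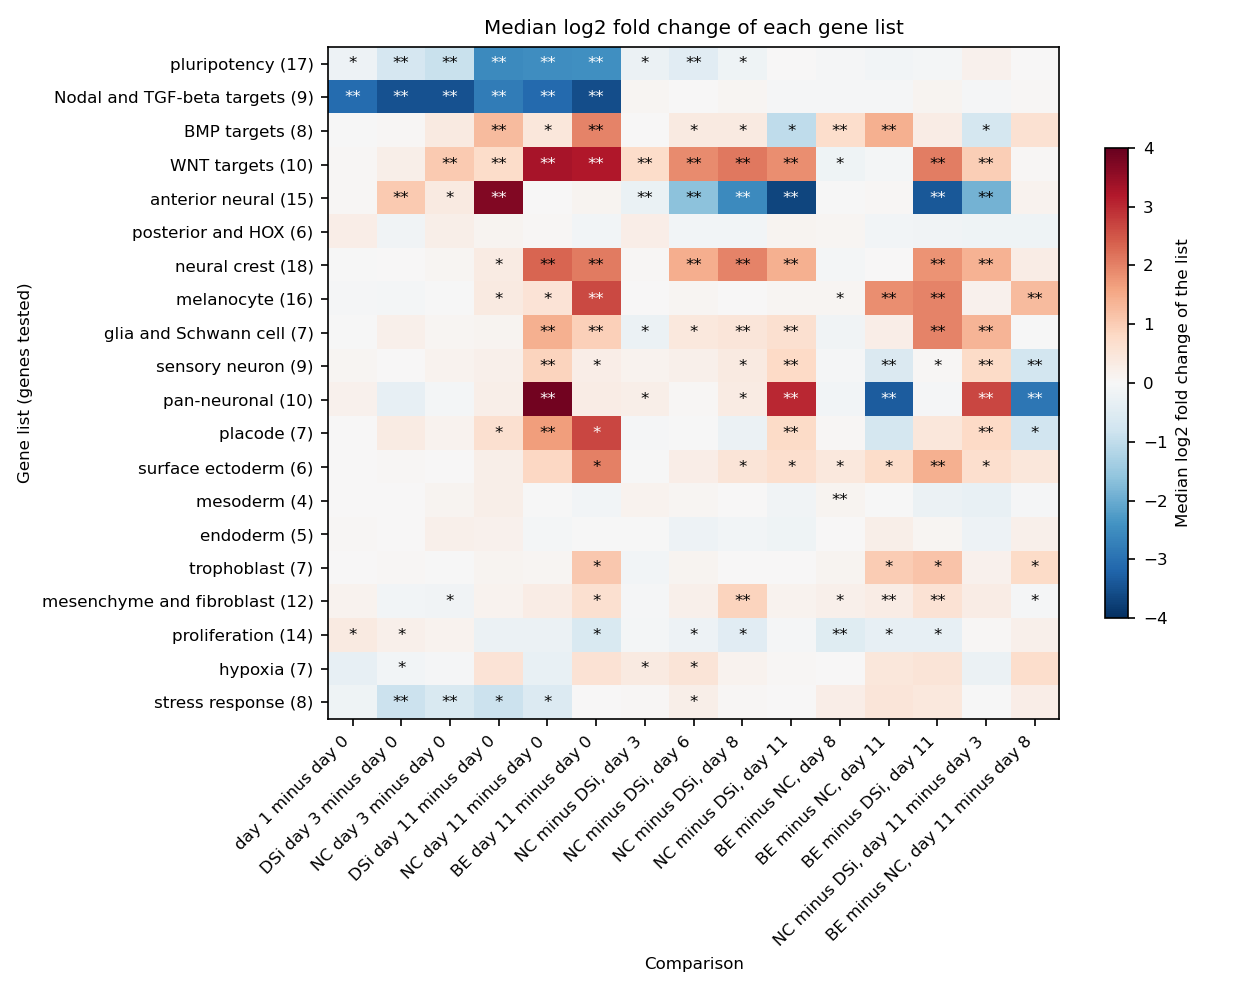
Median log2 fold change of 20 gene lists (vertical axis, with the number of genes tested) in the 15 comparisons (horizontal axis), red above and blue below 0; 1 asterisk marks lists past an adjusted p of 0.05 in the list test with a preset correlation, and a pair of asterisks those that also pass with an estimated correlation. Anterior neural genes had a median of 3.70 in DSi at day 11, and pan-neuronal genes one of 3.86 in NC at day 11.

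Hindbrain and more posterior identity genes were not called as a list by camera in any of the 15 comparisons, while fry called them higher at day 11 in NC (0.000709) and BE (0.0352) against day 0 and in NC against DSi (0.0174). The posterior and HOX list kept 6 tested genes; in the NC to DSi comparison at day 11 its median was 0.12, with 1 higher and 0 lower on either adjustment (camera adjusted p = 0.312). That gene was EGR2, which also works in Schwann cells, with a difference of 1.70 (SE 0.27). The endoderm list of 5 tested genes was not called by camera either: between BE and NC at day 11 its median was 0.24 (1 higher and 0 lower, 2 higher adjusted over the list alone; adjusted p = 0.0924, but 7.12e-05 with fry). Against day 0 fry called it lower in all 5 comparisons of days 3 and 11, among them DSi and NC day 11 (2.67e-08 and 7.39e-10), with 1 gene lower in each. Hypoxia genes moved both ways between DSi day 11 and day 0, 3 higher and 1 lower of 7 on either adjustment (median 0.54, adjusted p = 0.602); BNIP3 rose by 2.66 (SE 0.29) and ADM fell by 4.11 (SE 0.38).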

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

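Among the tests of this part, that of brighter or dimmer arrays and that of the 32 paired regroupings were chosen only after the result was seen. The NC to DSi difference changed between day 3 and day 11, by the test of the difference of differences, in 1240 genes. The largest changes toward NC were those of SYT4 (6.04, SE 0.45, adjusted p = 8.53e-14), POU4F1 (5.92, SE 0.41, adjusted p = 6.46e-15), SOX10 (5.74, SE 0.34, adjusted p = 4.28e-17) and ECEL1 (5.38, SE 0.43, adjusted p = 3.28e-13). Toward DSi they were LHX2 (-7.34, SE 0.35, adjusted p = 3.64e-20), DLK1 (-7.26, SE 0.44, adjusted p = 7.70e-17), HES5 (-5.86, SE 0.55, adjusted p = 3.26e-11) and SP8 (-5.55, SE 0.31, adjusted p = 1.09e-17). SOX10 differed by 0.01 at day 3 and was at least 33.5-fold higher in NC at day 11. The sizes in this paragraph are fitted differences, which are not exact where a gene was not above background in a group, as SOX10 in DSi at day 11. The BE to NC difference changed between day 8 and day 11 in 549 genes. TYRP1 (6.03, SE 0.41, adjusted p = 1.13e-14), MLANA (5.46, SE 0.34, adjusted p = 4.36e-16), DCT (4.43, SE 0.35, adjusted p = 7.22e-13) and TYR (4.34, SE 0.30, adjusted p = 1.43e-14) moved most toward BE. STMN2 (-4.85, SE 0.53, adjusted p = 4.90e-09), TNNC2 (-4.55, SE 0.28, adjusted p = 4.36e-16), RAB26 (-4.40, SE 0.39, adjusted p = 1.71e-11) and POU4F1 (-4.40, SE 0.41, adjusted p = 6.02e-11) moved most toward NC.

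In 100 regroupings of the arrays within days, 10, the real one included, gave at least 1240 genes for the change of the NC to DSi difference, and the highest other value was 1682. For the BE to NC difference 11 gave at least 549 genes, with 1197 as the highest other. The 9 and 10 others all kept the day 11 groups as they were and exchanged arrays of the earlier day, so the day 11 differences stayed in them. Because the scheme admits such regroupings, these counts cannot decide on chance, and they do not exclude it. Of the 32 regroupings that part every pair of same-numbered NC and DSi arrays on both days, 7, the real one included, gave at least 1240 genes, and the highest other gave 1648. Of the 32, 8 kept the day 11 groups, the real one and the 6 others as large among them, so this share cannot decide either. Those that exchanged day 11 arrays gave at most 15. For comparisons of 2 groups, 3 arrays against 3 make 10 splits, too few for a share under 0.05. Every other split mixes the 2 real groups, which shrinks a real difference and adds it to the spread. The size of the gap between the real count and the others therefore does not measure chance. Against day 0, day 1 gave 1006 genes and the highest other split 35, DSi day 3 gave 3820 against 0, NC day 3 gave 4362 against 5, DSi day 11 gave 6259 against 2, NC day 11 gave 6715 against 0, and BE day 11 gave 6583 against 1. Between NC and DSi, days 6, 8 and 11 gave 1230, 1527 and 2538 genes, with 36, 0 and 42 as the highest others. BE and NC gave 423 against 0 at day 8 and 2000 against 17 at day 11, and BE and DSi gave 3760 against 17. In each of these 1 of the 10 splits, the real one, gave as many. Between NC and DSi at day 3, 2 of the 10 splits gave 111 genes or more, and the other, with 135, exchanged NC replicate 1 with DSi replicate 2. Among the 4 splits that part all 3 pairs of same-numbered arrays, the highest other gave 1 gene there, 2 at day 6 and 4 at day 11, 0 between BE and NC at day 11 and 5 between BE and DSi. The predictions written beforehand covered all splits and not these 4, and the pairing was read from the same values. With 4 splits a share under 0.05 cannot be reached either.

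Neuronal genes stood apart in NC at day 11. Over 19 genes of the pan-neuronal and sensory neuron lists, the NC arrays had medians of 8.62, 9.29 and 9.25 on the log2 scale, against 5.10, 5.71 and 5.20 in DSi and 5.18, 5.27 and 6.13 in BE. A single deviating array was excluded as the cause, since the lowest NC array lay 2.50 above the highest of the others, and brighter or dimmer arrays were excluded, since the mean signal of 3 of 3 NC arrays lay in the range of the DSi and BE arrays. A candidate explanation, held as a hypothesis found in the same data, is that the NC cultures contained sensory neurons by day 11. The share of such cells was not measured, and whether BMP4 or EDN3 alone lowers these genes in BE cannot be read from a design that adds both.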

How the results depend on the processing

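Among named genes and gene lists, no value called before or after a change of setting reversed its direction, while values called in neither did in places, such as the placode list in BE against NC at day 11 with fry (adjusted p = 0.895). All alternatives were fixed beforehand. Among all genes called, a few were called the other way: 1 and 2 on the authors' values (DSi and BE day 11 against day 0), and 1 to 3 in 5 comparisons with day 0 with the mean over a gene's probes. The balance of higher and lower genes, near even in most comparisons, turned under several settings: with median scaling from 1070 and 930 to 893 and 944 for BE against NC at day 11, and on the authors' values from 552 and 454 to 492 and 549 for day 1. The counts of the 15 comparisons stayed within 1.5 times under no background correction, median scaling, cyclic loess, the authors' values, both filters, both treatments of several probes, both replicate blocks, no trend and the robust prior. Array weights raised day 1 against day 0 to 1554 genes and BE against NC at day 8 to 730. With only the compared arrays in the fit, NC against DSi gave 42 genes at day 3, 1683 at day 11 and 807 for the change between them. In these fits day 6 gave 855 and day 8 gave 1884, more than day 11. The order of days 8 and 11 thus depended on which arrays shared the estimate of spread. BE against NC at day 11 gave 1451 and BE against DSi 2521. Requiring a 2-fold change left 407 genes for day 1, 1448 and 1592 for DSi and NC day 3, 2777, 3004 and 3015 for DSi, NC and BE day 11 (all against day 0), 519, 741 and 1209 for NC against DSi at days 6, 8 and 11, 244 and 924 for BE against NC at days 8 and 11, and 1536 for BE against DSi; fewer genes meet a second condition by construction. Leaving out an array or a replicate number gave 304 to 819 genes for day 1, 2186 to 3525 and 2671 to 4274 for DSi and NC day 3, 22 to 163, 472 to 1095, 793 to 1296 and 1528 to 2301 for NC against DSi at days 3, 6, 8 and 11, 151 to 313 and 1053 to 1710 for BE against NC, 2378 to 3389 for BE against DSi, and 654 to 1280 and 279 to 541 for the changes of these differences. Fewer arrays lower the power by construction; for the other shifts the cause was not tested. The fit with the replicate number as a block called 135 genes for NC against DSi at day 3 and 7078 for NC day 11, and among the lists and the named genes it changed 5 list calls (3 lost, 2 gained), 3 gene calls (gained) and no other call, while among all genes it gained calls in every comparison and kept 6252 of 6259 for DSi day 11; the consensus correlation of the random block was 0.035. The lists it lost were WNT targets in BE against NC at day 8 (adjusted p = 0.0612), pan-neuronal in NC against DSi at day 3 (0.0512) and placode in the change of BE against NC (0.0512), and it gained hypoxia in BE against NC at day 11 (0.0374) and neural crest in the change of BE against NC (0.0483). Of 812 values of named genes, 44 calls were lost and 4 gained on the authors' values, 22 and 5 with median scaling, 27 and 4 without background correction, and 29 and 9 with only the compared arrays; the largest losses were 120 without replicate number 1, 97 with the 2-fold minimum, 87 without replicate number 2 and 68 without replicate number 3. Of 300 list tests, 51 calls were lost with an estimated correlation, 28 were lost and 4 gained with the stricter filter, 10 and 3 on the authors' values, and 4 and 32 with fry. Both replicate blocks gave a number the same level on all days. Same-numbered deviations correlated at 0.11 to 0.31 between NC and DSi at day 3, but at -0.03 to 0.06 between NC day 3 and day 0. A block for each number within a day was not run. The 2 blocks therefore do not show how far pairing within a day bears on the calls. The gene lists were not rerun with the random block, the robust prior or the 2-fold minimum, and slide as a block was not run because the tables name no slides. Signal over background limits dim genes: 34687 genes entered with no filter, 22850 with the filter used and 13954 with the stricter one.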

Other observations

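The tests of SOX10 and of ID1 and ID2 across normalizations were chosen only after the results were seen, as was 1 condition of the retinal test; the others were not. Genes passed through the cultures in different windows, described here as group means of normalized log2 signal (SD, n = 3). In NC, WNT1 stood at 4.45 ± 0.03 at day 3, at 10.21 ± 0.51 at day 6, at 9.81 ± 0.20 at day 8 and at 6.91 ± 0.65 at day 11. EDNRA stood at 10.99 ± 0.20 at day 8 and 9.06 ± 0.41 at day 11, and POU4F1 at 10.74 ± 0.09, 8.76 ± 0.21 and 11.59 ± 0.36 at days 6, 8 and 11. HESX1 in DSi stood at 9.77 ± 0.27 at day 3 and was detected on 0 of 3 arrays at day 11, while RAX stood at 5.77 ± 1.06 at day 3 and 10.34 ± 0.51 at day 6. EDNRB stood at 9.57 ± 0.16 at day 0, at 5.47 ± 0.83 in NC at day 3 and at 9.84 ± 0.21 in NC and 11.11 ± 0.39 in BE at day 11. These levels were not tested between days within a condition. In the trophoblast list, the hormone subunit gene CGA was higher in BE than in NC at day 11 by 2.01 (SE 0.58, adjusted p = 0.0197), at 8.89 ± 2.03 against 6.88 ± 1.22. This call was lost without BE replicate 1 (adjusted p = 0.0673), BE replicate 2 (0.387), NC replicate 1 (0.0547) or NC replicate 3 (0.216), without replicate number 1 of all groups (0.259), with only the compared arrays (0.0778) and with the robust prior (0.107).

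Pigment genes were found in DSi at day 11, where DCT stood at 9.78 ± 0.51 and TYRP1 at 7.16 ± 1.16, while MLANA was detected on 0 of 3 arrays. SOX10, detected on 0 of 3 DSi arrays and at least 30.1-fold higher in BE (fitted difference -5.60, SE 0.24, not exact at background), argued against neural crest cells as the source, while the neural crest list was higher in DSi at day 11 than at day 0 in 7 of 18 cases and lower in 2 (list test 0.0399, but 0.353 with an estimated correlation, 0.139 on the authors' values and 0.0649 without replicate number 3). Every DSi day 11 array carried the DCT signal, since the lowest lay 4.37 above the highest DSi array at day 8. The signal therefore did not rest on 1 or 2 mixed-up arrays. DCT could not reveal an exchange with the BE arrays of day 11, whose level was alike. SOX10 and MLANA, both high in BE and detected on 0 of 3 DSi arrays, argued against such an exchange. Retinal pigment cells stay open. Of the 12 genes of a retina list 8 were tested, and 3 of these were higher in DSi than in BE. They were RAX by 5.18 (above background on 1 of 3 BE arrays), SERPINF1 by 2.06 and SIX6, which was not above background in BE. The 2 lower were TRPM3 at -1.60 and BEST1, which was detected on 0 of 3 DSi arrays. LRAT and TTR were also detected on 0 of 3 DSi arrays and RGR on 1 of 3, and none of them was called. The median over the list was 0.09, and RAX and SIX6 also belong to the anterior neural list. The values foreseen for this explanation, a median above 0 and a set test passed upward before any adjustment, were met. The sign of the median decides nothing, since it lies between RGR (0.07, SE 0.21) and LRAT (0.10, SE 0.27), both within their error of 0. The set test was not run without RAX and SIX6, so it cannot tell retinal pigment cells from anterior neural cells. The condition that no member be called lower, added after the result was seen, was not met, already for TRPM3. The hypothesis that some DSi cells may be heading to retinal pigment epithelium remains untested by cell-level data.

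Of the BMP targets, ID1 and ID2 rose in DSi after day 3. From day 3 to day 6 only these 2 of the 8 targets passed, ID1 with 4.27 (SE 0.31, adjusted p = 1.48e-14) and ID2 with 1.20 (SE 0.19, adjusted p = 4.24e-06), and the list had a median of 0.41 (list test 0.000638, but 0.0790 with an estimated correlation); in NC 4 of 8 passed, with a median of 0.80 (5.32e-05 and 0.0580). Background correction or normalization was excluded as the cause for ID1 and ID2, whose lowest rise over the other 4 normalizations was 1.02, while for the list as a whole the test of normalization, with a lowest median of 0.22, decided nothing, because the bound set for it beforehand lay above even the reported median. A relief of the inhibition of both receptor classes could not be told apart from other causes, as the Nodal and TGF-beta targets had a median of 0.11, nor could a rise of the ID genes alone, as the other targets had a median of 0.17. The upward set test foreseen for such a relief was not passed: 1 Nodal and TGF-beta target rose and 1 fell (list test 0.641). In NC that list had a median of -0.02 (list test 0.936). The DSi day 3 array whose title lacks the suffix of the others, replicate 1, had the highest ID1 of the 3 (7.51 against 5.91 and 6.16), and the labels do not give the timing of the compounds, so the cause of the rise stays open.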
